A study of Zea mays with 36 samples.

How the data were processed

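The study followed the transcriptome of the developing maize embryo in a line with high oil content and a line with low oil content. Embryos were sampled every 5 days from 15 to 40 days after pollination, which makes 6 stages, with 3 replicates per line and stage, giving 12 groups and 36 libraries. Per the labels' protocols, seeds were left in water overnight at room temperature before each embryo was separated from its endosperm and frozen. Polyadenylated RNA was selected with oligo(dT) beads, the libraries were built with the NEBNext Ultra kit and sequenced as paired ends on an Illumina HiSeq instrument. Groups, stages and replicate numbers were taken from the labels. The labels do not say whether the replicates of a group came from separate plants or ears, so the p-values measure the spread between these samples, which may be partly technical.

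The authors deposited 1 table of RPKM values (reads scaled by feature length and by library total) with 1 column per library, and 0 of its columns were left unused. FastQC, TopHat2 and Cufflinks and the genome build B73 RefGen_v4 are named, without versions or roles, per the submitters' processing notes. The counting tool, the annotation release and the use of strand are not given in the sources used here. The table holds 63340 features in 5 classes: 44146 annotated gene IDs, 17005 features that carry a running number in place of an annotation ID, 1861 noncoding RNA IDs with the Ensembl prefix ENSRNA, 154 microRNA precursors with their names, and 174 older GRMZM IDs that were listed at 0 throughout.

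The deposited RPKM values keep the depth of each library. Within a library, the values of a feature were whole multiples of what 1 read is worth, and 100% of the 51853 features with any value above 0 resolved to whole reads in all 36 libraries within a tolerance of 0.0001 reads. The implied library totals ran from 41247297 to 66760746, and the recovered reads of a library summed to its total with a difference of at most 1217 reads. The denominator was therefore the number of reads assigned to features. Whether a read here is a single end or a fragment could not be told from the values. For a feature of 1000 bases, 1 RPKM stood for 41.2 to 66.8 reads. Limits for features without reads were set at 3 reads over the group of libraries, and intervals of read ratios are exact binomial intervals. Both cover counting error only, since reads amplified by PCR are not independent molecules.

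Because RPKM values are not counts, the main test was limma on log2(RPKM + 1), with a pseudocount of 1, 1 mean per group over all 36 libraries, and empirical Bayes moderation with a mean-variance trend. A fold change is on the log2(RPKM + 1) scale and understates the change of low features. Features with at least 1 RPKM in at least 3 libraries were tested, which left 28048, of which 23757 were annotated gene IDs, 3982 running numbers, 292 ENSRNA IDs and 17 microRNA precursors. P-values were adjusted by the Benjamini-Hochberg method over the features of each comparison. A feature was called when the adjusted p was below 0.05 and the change was at least 1 on the log2 scale. The comparisons were the line difference at each of the 6 stages and averaged over them, the 5 changes between neighbouring stages averaged over lines, the change from 15 to 40 days in each line, and the interaction of line with that change. These tests, the filter, the thresholds and most alternative settings were fixed before the data were examined. These settings were median-of-ratios scaling, quantile normalization, a pseudocount of 0.1, no filter, a minimum of 5 RPKM, the adjusted p alone, a fit of the compared groups only, the replicate number as a block, and each library left out in turn. Limma-voom on the recovered reads, and a fit without 3 libraries that stand apart from their groups, were added after the data were seen.

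The test was checked on reads simulated from the real means, spreads and library totals, with 200 changed features per simulation. The changed features were drawn among those with a mean of at least 2 RPKM, and features were simulated independently of each other. Recovery among lower features was therefore not measured, and 4999 of the 28048 tested features had a mean below 1 RPKM. For the line difference at 25 days, run on 27340 features, 84% of the 4-fold changes and 25% of the 2-fold changes were recovered in the right direction, with 18 false calls. For the line difference averaged over stages, run on 27141 features, 95% of the 4-fold and 18% of the 2-fold changes were recovered, with 0 false calls. The minimum of 1 log2 unit on the log2(RPKM + 1) scale excludes many true 2-fold changes.

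Gene names were a limit. The files used here do not pair the annotated gene IDs with names: 0 of the 44146 IDs matched the reference table of 49888 genes, which belongs to another assembly. The 21 gene lists fixed before the data were examined, cell type markers among them, were defined by names and could not be evaluated, so RNA from endosperm or seed coat in the dissected embryos was not tested. The rule for named genes asked for an informative name. It was applied here without that part: the 2 highest and 2 lowest log2 changes among called annotated gene IDs with a mean of at least 10 RPKM in at least 1 group compared, with the same sign at all 6 stages for the averaged line difference. The microRNA precursors are the only features with names and were all examined, a choice made after the data were seen, as was Zm00001d033447, named because it carried a difference in the share of reads. A precursor is a short feature inside a longer transcript, and reads of an overlapping gene on either strand cannot be told apart from it. Near-identical gene copies may share reads in an unknown way.

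No replicate pair of a group looked like 1 library deposited more than once. Over features with at least 20 reads in a pair, the median squared deviation of their reads from equal proportions was 5.4 to 25.9, against 0.455 for sampling noise alone. Summaries per library were compared between lines by exact permutation within a stage, where 3 against 3 libraries cannot give a two-sided p below 0.1, and by 100000 permutations of the line within each stage over all 18 libraries per line. Overlaps of lists were set beside the overlap of independent lists. Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.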

Results

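Embryo transcriptomes of the high-oil and low-oil maize lines were sampled at 6 stages between 15 and 40 days after pollination, in 3 libraries per line and stage. Library totals lay between 41247297 and 66760746 reads assigned to features. Between 21757 and 22508 features per group, on average, reached 1 RPKM. Stage was the main axis of variation: the first principal component of the log2 values held 46.4% of the variance and ordered the stage means, and the second held 17.5% and separated the lines. Of the 36 libraries, 3 stood apart by the lowest mean correlations to their own group. They were high-oil 35-day replicate 2 (0.938), high-oil 40-day replicate 1 (0.934) and low-oil 40-day replicate 1 (0.941). No clear gap set them off: high-oil 35-day replicate 1 had 0.944 and low-oil 25-day replicate 3 had 0.946. The late groups overlapped. All high-oil 35-day libraries, and some other 35-day and 40-day libraries of both lines, correlated best with a library of another stage. Low-oil 40-day replicate 1 correlated best within its own group.

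The reads became concentrated in fewer transcripts between 15 and 25 days. The 10 features with the highest RPKM of each library took 5.47% ± 0.711 (SD, n = 3) of its reads at 15 days in the high-oil line and 4.86% ± 0.5 in the low-oil line. At 25 days they took 26.1% ± 1.44 and 19.3% ± 0.493, and at 40 days 20.5% ± 2.78 and 15.7% ± 1.16. The share was higher in the high-oil line at all 6 stages, by a mean of 4.51 percentage points (permutation p = 1e-05, the smallest the resamples can give, two-sided, 18 libraries per line). For 1 fixed set, the 10 features with the highest mean over all libraries, the lines differed by 5.19 points (permutation p = 1e-05, adjusted p = 4e-05 over 4 summaries). That set favours features abundant from 25 days on, so its own rise from 15 days is partly built in. Only 1 of this set was called between the lines averaged over stages, and it carried most of the difference. This gene, Zm00001d033447, had 28700 ± 15300 RPKM in the high-oil line and 531 ± 258 in the low-oil line (SD, n = 18; 54.1-fold, log2 5.49, SE 0.14, adjusted p 4.6e-24). It took 4.09% of the reads in the high-oil and 0.0756% in the low-oil libraries, 4.01 of the 5.19 percentage points. Without it the share of the other 9 differed by 1.18 points, higher in the high-oil line at 4 of 6 stages (permutation p = 0.069, two-sided, 18 libraries per line). The log2 difference was above 0 for 5 of the set. Both sets of 10 and this gene were chosen after the values were seen.

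**Figure D1:**
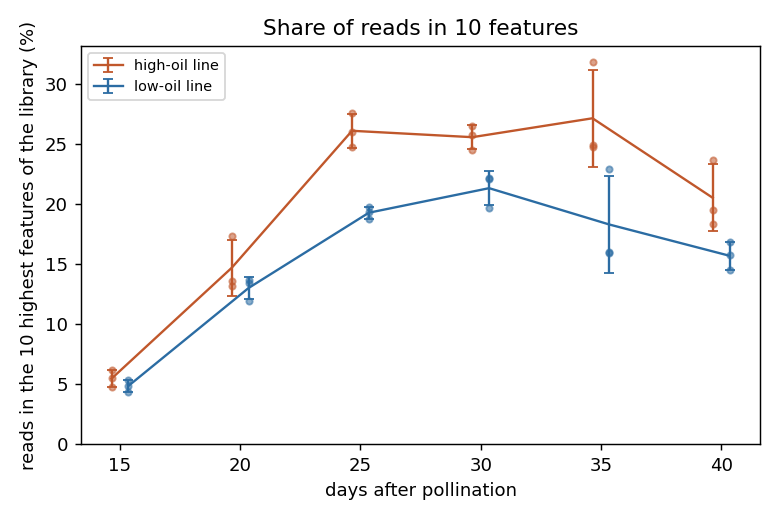
Percent of the reads of each library that fell in its own 10 features of highest RPKM (vertical axis) by days after pollination (horizontal axis). Points are libraries, lines join group means and bars are 1 SD (n = 3), in orange for the high-oil and blue for the low-oil line, shifted sideways for legibility. The share went from 5.47% at 15 days to 26.1% at 25 days in the high-oil line and from 4.86% to 19.3% in the low-oil line.

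The comparison of the oldest with the youngest embryos asked how the transcriptome changed over seed filling in each line. All seeds had been left in water overnight, and a response to soaking that differs with age was not tested apart from development. In the high-oil line 8834 features were called between 15 and 40 days, of which 2884 rose and 5950 fell, and in the low-oil line 9070 were called, of which 3077 rose and 5993 fell (limma, adjusted p below 0.05 and at least 1 log2 unit). The balance between rises and falls depended on the scaling. Values scaled by the total reads are lowered where a few features fill the total, and the median log2 change of all features was -0.24 in both lines. With median-of-ratios scaling 3923 rose and 3868 fell in the high-oil line, and 4112 rose and 3869 fell in the low-oil line. The lists of the 2 lines overlapped in 2097 features that rose in both and 4646 that fell in both, against 316 and 1270 for independent lists, and 16 changed in opposite directions. With median-of-ratios scaling 2863 rose and 2930 fell in both, so the excess of falls depended on the scaling. The log2 changes of the lines correlated across features with r = 0.89 (features are not independent replicates).

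Among transcripts that were abundant at either end, more rose than fell. Of the 119 features with a mean of at least 1000 RPKM at 15 or at 40 days in the high-oil line, 63 rose and 37 fell, and of the 117 in the low-oil line, 68 rose and 26 fell. With median-of-ratios scaling 75 rose and 25 fell of 118, and 73 rose and 15 fell of 108. In the high-oil line 62 features stood at or above 1000 RPKM at 15 days and 75 at 40 days, and in the low-oil line 51 and 84. The limit was applied to both ends alike, after the values were seen, because a limit on the mean over all stages favours features that rise early.

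The largest rises and falls were of about the same size in both lines. The annotated gene Zm00001d007299 rose from 4.23 ± 0.306 to 9620 ± 2740 RPKM (SD, n = 3) in the high-oil line and from 3.83 ± 0.883 to 9020 ± 3550 in the low-oil line, changes of 2280-fold and 2350-fold (log2 10.80, SE 0.62, adjusted p 2.1e-14, and log2 10.81, SE 0.62, adjusted p 2.6e-14). Zm00001d048629 rose from 1.62 ± 0.0341 to 2770 ± 304 RPKM in the high-oil line and from 1.7 ± 0.391 to 4080 ± 216 in the low-oil line (log2 10.04, SE 0.30, and 10.57, SE 0.30). Zm00001d029526 fell from 632 ± 98.7 to 0.328 ± 0.392 RPKM in the high-oil line and from 436 ± 111 to 0.215 ± 0.231 in the low-oil line (log2 -8.92, SE 0.54, and -8.48, SE 0.54). Zm00001d030530 fell from 876 ± 189 to 2.33 ± 1.28 RPKM and from 775 ± 177 to 2.29 ± 0.336 RPKM (log2 -8.11, SE 0.42, and -7.86, SE 0.42). The adjusted p of these last 3 genes was at most 1.5e-13 in either line. The IDs could not be tied to gene names with the files used here.

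Features without an annotation ID moved differently from annotated genes. Among those that carry a running number, 619 rose and 226 fell from 15 to 40 days in the high-oil line, a share of rises of 73.3%, against 28.1% of the called annotated genes (Fisher's exact test, odds ratio 7.01, p = 2e-145, with features treated as independent, which they are not). In the low-oil line 649 rose and 273 fell, 70.4% against 29.7% (Fisher's exact test, odds ratio 5.62, p = 5.9e-127). With median-of-ratios scaling the shares were 84.0% against 45.7% in the high-oil line and 82.1% against 47.3% in the low-oil line. Of the 292 ENSRNA noncoding RNA features, 32 rose and 6 fell in the high-oil line and 16 rose and 12 fell in the low-oil line, and 48 and 4, and 28 and 8, with that scaling.

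Each of the 2 earliest intervals had more calls than any later one. Averaged over lines, 668 features rose and 811 fell between 15 and 20 days, and 635 rose and 848 fell between 20 and 25 days. Then 104 rose and 150 fell between 25 and 30 days, 207 rose and 284 fell between 30 and 35 days, and 117 rose and 80 fell between 35 and 40 days. With median-of-ratios scaling the split turned to 776 rises and 497 falls for the earliest interval, to 761 and 578 for 20 to 25 days, to 133 and 108 for 25 to 30 days, and to 100 and 110 for 35 to 40 days. The median log2 change of all features was -0.11 in each of the 2 earliest intervals before that scaling. Of the 2097 features that rose in both lines, the median one had made 20.4% of its log2 change by 20 days and 52.4% by 25 days. It had made 68.6% by 30 days and 86.0% by 35 days. For the 4646 that fell in both, these values were 29.3%, 60.8%, 78.8% and 94.5%. On these values, scaled by total reads, the rises went on through the later stages and the falls leaned more to the early ones. The timing was not computed with median-of-ratios scaling, so whether this contrast depends on the scaling was not tested. The last interval was the least certain: its count of 197 became 0 when only the compared groups were fitted (limma, 3209 features at an unadjusted p below 0.05), and it was 101 without low-oil 40-day replicate 1 and 339 without low-oil 40-day replicate 3. The count for 25 to 30 days fell from 254 to 155 without high-oil 25-day replicate 2.

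**Figure D2:**
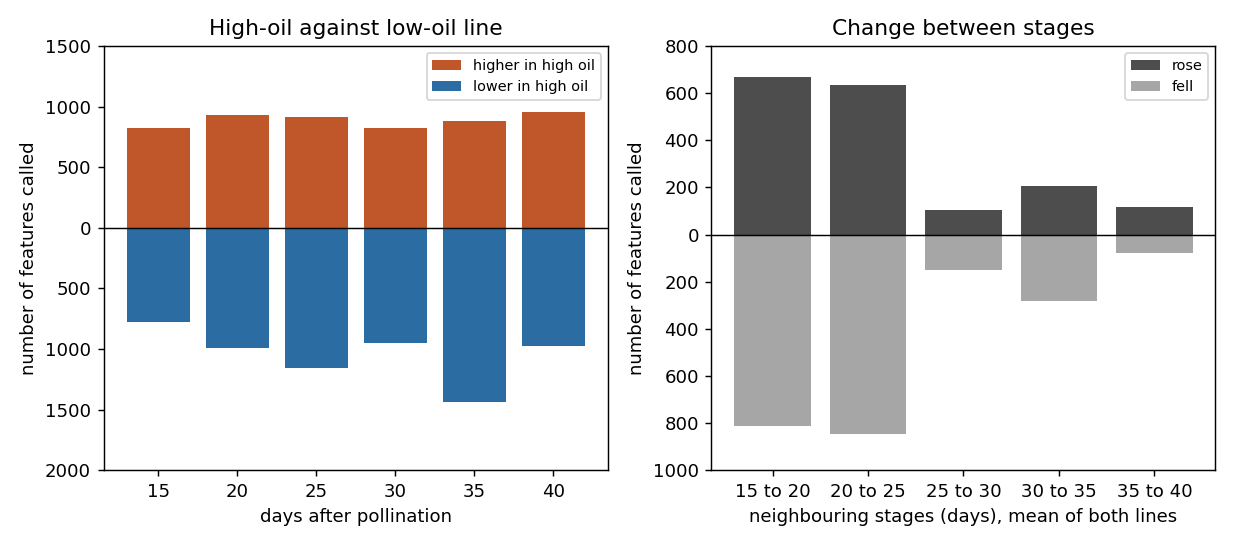
Number of features called (vertical axis) between the lines at each stage (left, days after pollination) and between neighbouring stages averaged over lines (right). Bars above 0 are features higher in the high-oil line or at the later stage and bars below 0 are lower, with 28048 features tested. Line differences numbered 1603 to 2319 at every stage, while changes between stages dropped from 1479 and 1483 in the 2 earliest intervals to 197 in the last.

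No line difference in the mean level of a score of this change passed the test, which does not show that the levels were equal. The test averaged the line difference over the stages, so pace itself was not tested. A score per library, the mean log2 value of the features that rose in both lines minus that of the features that fell in both, went from -2.75 ± 0.161 (SD, n = 3) at 15 days to 1.68 ± 0.226 at 40 days in the high-oil line and from -2.65 ± 0.0351 to 1.78 ± 0.424 in the low-oil line. The high-oil line lay lower at 5 of 6 stages, by a mean difference of -0.132 (permutation p = 0.071, adjusted p = 0.12, two-sided, 18 libraries per line). The widest gap was at 30 days, 0.34 ± 0.26 against 0.713 ± 0.118, with values that did not overlap (exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). The features of the score were chosen because they changed in the same direction in both lines, so similar values at 15 and 40 days are partly built in.

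**Figure D3:**
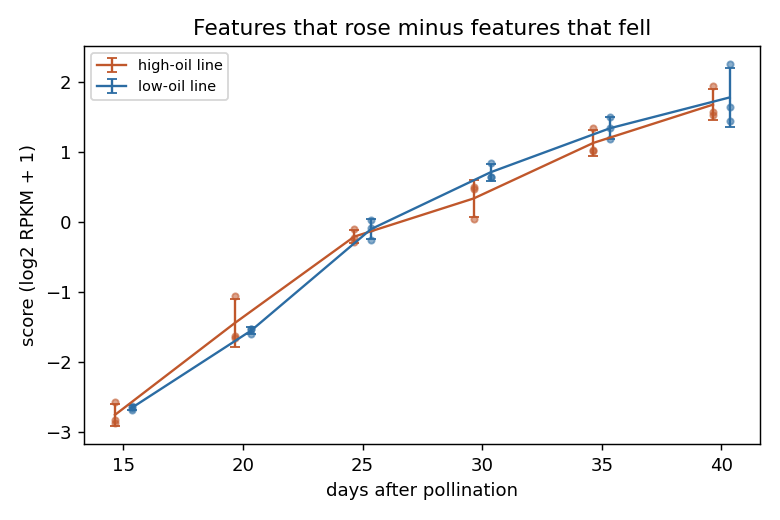
Score of developmental progress (vertical axis, difference of mean log2(RPKM + 1) between features that rose and features that fell from 15 to 40 days in both lines) by days after pollination. Points are libraries, lines join group means and bars are 1 SD (n = 3), in orange for the high-oil and blue for the low-oil line. Both lines climb from about -2.75 and -2.65 at 15 days to 1.68 and 1.78 at 40 days.

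Named microRNA precursors changed in opposite directions during development. MIR168a, of a family that targets ARGONAUTE1 transcripts, rose from 0.155 ± 0.269 RPKM at 15 days to 28.1 ± 2.42 at 40 days in the high-oil line (SD, n = 3; log2 4.68, SE 0.52, adjusted p 1.1e-08). With 2 reads at 15 days and 518 at 40 days, the ratio of pooled reads was 203 with a 95% counting interval of 55.9 to 1680. In the low-oil line MIR168a rose from 1.17 ± 0.829 to 21.8 ± 19 RPKM (log2 3.06, SE 0.52, adjusted p 1.2e-05). MIR156e, of a family that targets SPL transcription factor transcripts, fell from 6.21 ± 2.6 to 0.148 ± 0.154 RPKM in the high-oil line (log2 -2.58, SE 0.45, adjusted p 1.7e-05; 105 reads against 3, ratio 44.7, interval 14.9 to 220). In the low-oil line it fell from 8.91 ± 2.19 to 1.57 ± 2.28 RPKM (log2 -2.29, SE 0.45, adjusted p 8.2e-05). MIR156i fell in the low-oil line (log2 -1.38, SE 0.46, adjusted p 0.011), a call that ended without low-oil 15-day replicate 2 (log2 -1.01, adjusted p 0.091). MIR2118c, of a family that triggers phased small RNAs, fell in the low-oil line from 7.45 ± 3.12 to 1.38 ± 0.697 RPKM (log2 -1.80, SE 0.40, adjusted p 0.00038). In the high-oil line its log2 value of -1 (adjusted p 0.036) was no longer called with median-of-ratios scaling (log2 -0.67, adjusted p 0.16). Of the 17 precursors tested, 1 rose and 3 fell in each line, and with that scaling 1 rose and 2 fell in the high-oil line and 3 rose and 3 fell in the low-oil line. Adjusted over the list alone, 3 in the high-oil and 5 in the low-oil line had an adjusted p below 0.05, against 4 and 5 adjusted over all features.

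The comparison of the lines asked how embryos of the high-oil and the low-oil line differ at the same age. Each oil level was represented by a single line, so oil content cannot be told apart from other genetic differences between the lines. The libraries replicate these lines and not oil content. At 15 days 827 features were higher and 776 lower in the high-oil line, at 20 days 927 and 993, at 25 days 910 and 1155, at 30 days 820 and 947, at 35 days 881 and 1438, and at 40 days 955 and 974. At 25 days the split turned to 1086 higher and 889 lower with median-of-ratios scaling, where the median log2 difference of all features moved from -0.13 to 0.01. At 30 days the split became 920 and 913, at 35 days, where that median was -0.11, 1102 and 1205, and at 40 days 1047 and 933. At 40 days 1249 features were called when only the compared groups were fitted, against 1929.

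A core of line differences was present at every age. At all 6 stages, 321 features were higher and 306 lower in the high-oil line. Independent lists would share 2.8e-05 and 6.8e-05. These lists compare the same lines in a single fit, so an overlap above that was built in. Of the 4819 features called at 1 or more stages, 48.1% were called at a single stage and 13% at all 6 in 1 direction, and 63 were called in both directions at different stages. The line differences at 35 and 40 days resembled each other most, with a correlation across features of 0.84. The correlation was 0.75 between 30 and 35 days, 0.74 between 15 and 20 days, 0.73 between 30 and 40 days and 0.56 between 15 and 40 days. No library was shared between stages. High-oil 35-day replicate 2 and high-oil 40-day replicate 1, which stood apart from their groups, correlated with each other (0.961), and whether this raised the 0.84 was not tested.

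Averaged over stages, 803 features were higher and 831 lower in the high-oil line, which turned to 852 and 756 with median-of-ratios scaling and 848 and 778 with quantile normalization. The count of 1634 was 3451 with a pseudocount of 0.1 and 3701 with limma-voom on the recovered reads, 1608 of them shared in the same direction. The annotated gene Zm00001d025423 had 165 ± 21.5 RPKM in the high-oil line and 0.263 ± 0.172 in the low-oil line (SD, n = 18; 627-fold, log2 7.04, SE 0.07, adjusted p 6.3e-34). Zm00001d041663 had 275 ± 105 against 3.55 ± 2.86 RPKM (77.5-fold, log2 5.98, SE 0.11, adjusted p 1.5e-27). Zm00001d028330 had 0.11 ± 0.0988 RPKM in the high-oil line and 53.0 ± 9 in the low-oil line (482-fold lower, log2 -5.59, SE 0.06, adjusted p 8.4e-33). Zm00001d033948 had 0.0672 ± 0.0681 against 45.2 ± 14.2 RPKM (673-fold lower, log2 -5.37, SE 0.07, adjusted p 8.1e-31). The rule that picked these 4 required the same direction at all 6 stages. The SD includes the change between stages. Zm00001d025423, Zm00001d028330 and Zm00001d033948 lay below 1 RPKM on average in the lower line. Alignment to a single reference genome can lower the values of a line, and its part in these folds was not tested.

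Line differences were more frequent among features with a running number than among annotated genes. Of the 3982 with a running number, 316 were higher and 236 lower in the high-oil line, 13.9% in all, against 468 higher and 575 lower, 4.39%, of the 23757 annotated genes (Fisher's exact test, odds ratio 3.5, p = 3.5e-98, features not independent). Of the 292 ENSRNA features, 17 were higher and 20 lower, 12.7% in all, so the higher share was not particular to features with a running number. The share called also varied with mean RPKM, with 8.26% at 1 to 10 RPKM and 3.39% at 10 to 100. The classes were not matched on level or length for this comparison. At the extreme, 81 features were listed at 1 RPKM or more in all 18 high-oil libraries and below 0.1 in all 18 low-oil libraries, 52 of them with a running number, and 57 showed the reverse, 36 of them with a running number. No test goes with these counts, and alignment of both lines to a single reference genome can lower the values of a line whose copy of a gene differs from it or is absent. Only 3 features had 0 RPKM in all libraries of the other line.

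The precursors of 2 microRNAs were called higher in the high-oil line averaged over stages. MIR164c, of a family that targets NAC transcription factor transcripts, had 6.63 ± 0.471, 9.29 ± 4.99, 5.35 ± 2.18, 2.13 ± 1.47, 0.994 ± 1 and 0 RPKM from 15 to 40 days in the high-oil line (SD, n = 3 each). In the low-oil line it had 0.0529 ± 0.0461 and 0.0712 ± 0.123 RPKM at 15 and 20 days and 0 reads in the 12 later libraries. Over all stages 948 reads faced 5, a ratio of 197 with a 95% counting interval of 84.2 to 609 (log2 1.82, SE 0.14, adjusted p 7.8e-12). It was called at 15, 20, 25 and 30 days and not at 35 days (log2 0.86, adjusted p 0.1) or 40 days. MIR408b, of a family that targets transcripts of copper-binding proteins, had 33.5 ± 18.8 RPKM in the high-oil line and 1.18 ± 0.955 in the low-oil line at 15 days. At 25 days it had 7.81 ± 4.24 against 5.65 ± 4.39, and at 40 days 17.1 ± 8.59 against 2.43 ± 1.87 (averaged log2 2.22, SE 0.30, adjusted p 4.6e-07). It was called at 15, 35 and 40 days. Averaged over stages, 2 of the 17 precursors were called higher and 0 lower, and 5 had an adjusted p below 0.05 both over all features and adjusted over the list alone. The other 3, below 1 log2 unit, were also higher in the high-oil line: MIR2118c (log2 0.63, SE 0.16, adjusted p 0.0033), MIR168b (0.54, SE 0.19, adjusted p 0.027) and MIR167a (0.32, SE 0.10, adjusted p 0.019). MIR167a had 50 reads in the high-oil line and 0 in the 18 low-oil libraries, and its low RPKM keeps the log2 value small. With a pseudocount of 0.1 it was 1.23 and with limma-voom 1.63, both past the threshold. The calls of MIR164c and MIR408b held under each scaling. At single stages MIR168b was also called higher in the high-oil line at 35 days (limma, log2 1.59, SE 0.45, adjusted p 0.016). MIR319d was called lower in the high-oil line at 20 days (limma, log2 -1.13, SE 0.36, adjusted p 0.041), with 5 reads against 51.

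**Figure D4:**
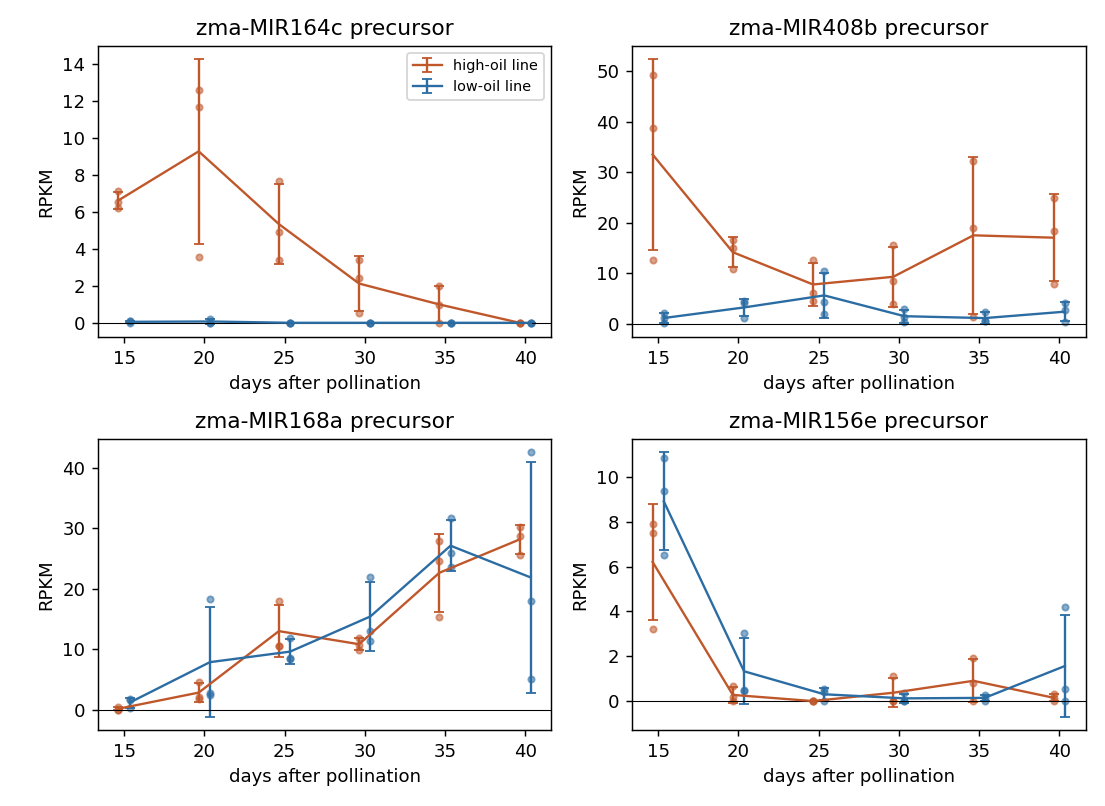
RPKM of the precursors of MIR164c, MIR408b, MIR168a and MIR156e (vertical axes, separate scales) by days after pollination. Points are libraries, lines join group means and bars are 1 SD (n = 3), in orange for the high-oil and blue for the low-oil line, shifted sideways for legibility. MIR164c reaches 9.29 in the high-oil and 0.0712 in the low-oil line at 20 days, while MIR168a rises to 28.1 and 21.8 at 40 days.

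The interaction asked which features changed differently in the lines between 15 and 40 days. It called 769 features, 370 with a more positive change in the high-oil line and 399 with a more negative one. Of these, 156 rose and 156 fell only in the high-oil line by the calls, 147 rose and 124 fell only in the low-oil line, 54 rose and 68 fell in both by different amounts, 16 changed in opposite directions and 48 were called in neither line. Zm00001d000636 rose from 0.0199 ± 0.0345 to 124 ± 32.6 RPKM in the high-oil line (SD, n = 3) and had 0.0414 ± 0.0717 and 0.174 ± 0.0698 in the low-oil line (difference of log2 changes 6.73, SE 0.98, adjusted p 4.8e-05). Zm00001d017292 had 69.8 ± 9.05 RPKM at 15 days in the low-oil line, where it ended at 0.0376 ± 0.0651, and 0.0739 ± 0.0553 and 0.00906 ± 0.0157 in the high-oil line (6, SE 0.67, adjusted p 8.6e-07). Zm00001d013937 went from 43.3 ± 11.1 to 9.6 ± 5.27 RPKM in the high-oil line and from 2.55 ± 1.16 to 42.7 ± 11.7 in the low-oil line (-5.78, SE 0.53, adjusted p 3.5e-08). Zm00001d046667 went from 79.5 ± 12.8 to 7.97 ± 4.49 RPKM in the high-oil line and from 41.5 ± 22 to 182 ± 150 in the low-oil line (-5.25, SE 0.65, adjusted p 4.7e-06). MIR164c fell in the high-oil line from 6.63 ± 0.471 RPKM to 0 reads, at least 105-fold at a limit of 3 reads over the group, and the low-oil line stood at 2 and 0 reads (-2.86, SE 0.49, adjusted p 0.00041). Limma-voom on the recovered reads called 320 features, 285 of them shared with the 769 in the same direction, and ended the calls of Zm00001d000636 (9.68, SE 5.08, adjusted p 0.53), Zm00001d017292 (9.29, SE 3.62, adjusted p 0.3) and MIR164c (-6.31, SE 2.01, adjusted p 0.15). These differences were larger than in the test on RPKM, but so were their SE, with at most 2 reads in the lowest of the 4 groups. With a minimum of 5 RPKM the count was 495.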

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

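The change from 15 to 40 days differed between the lines for 769 features by the interaction test, and 16 features had called changes in opposite directions. The features picked by the fixed rule were Zm00001d000636 (6.73 on the log2 scale, high-oil change minus low-oil change), Zm00001d017292 (6), Zm00001d013937 (-5.78) and Zm00001d046667 (-5.25), and MIR164c (-2.86), which was singled out after its values were seen. They stand here because the lines differ in the direction or size of the same change. Dixon's test for single deviating libraries was not run, since no group has more than 3 libraries.

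Splits of the libraries did not decide whether chance accounts for the count of the interaction. When line labels were exchanged between libraries within 15 and within 40 days, 12 of 100 splits drawn, the real one included, gave as many calls, with 1860 as the highest other count against the real 769. The 81 splits that mixed the lines at both ages gave at most 38 calls. The 11 other splits with as many calls were all among the 18 that mixed the lines at 1 age and left the lines whole at the other. In such a split the steady line difference at the unmixed age enters the contrast, so these counts point to the structure of the samples and are no measure of chance for an interaction. Exchanging the lines whole at 15 days, which turns the contrast into a sum of 2 line differences, gave 3270 calls.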

How the results depend on the processing

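Limma-voom, the fit without 3 libraries that stand apart, and the alternatives of derived counts and of the share of abundant features were chosen after seeing the data. Of 844 alternatives of 37 results for single features, 831 kept the direction and the side of the threshold, 11 lost the call, 2 gained it and 0 reversed. The gains were MIR167a between the lines with a pseudocount of 0.1 (1.23) and with limma-voom (1.63). The losses were MIR2118c in the high-oil line (log2 -0.46 to -1.23 where lost), MIR156i in the low-oil line (-1.01) and 3 interaction results under limma-voom, whose log2 differences grew, Zm00001d000636 (9.68, SE 5.08), Zm00001d017292 (9.29, SE 3.62) and MIR164c (-6.31, SE 2.01). The numbers showed no pairing across the stages. No stage had all 3 same-numbered correlations of deviations between lines above 0.1, and 1 of 30 pairs of stages within a line did. Of 36 libraries, 14 correlated best with their own number in the other line. A factor shared by number at single stages is not excluded. The 3 correlations were 0.39, 0.31 and 0.1 at 40 days and 0.14, 0.16 and 0.09 at 30 days, but -0.11, -0.3 and -0.19 at 35 days. With the replicate number as a block the counts were 1597, 1918, 2072, 1767, 2305 and 1925 for the line differences from 15 to 40 days, 1635 for their average, 1478, 1483, 259, 497 and 200 for the 5 successive intervals, 8828 and 9075 for 15 to 40 days in the high-oil and low-oil lines and 754 for the interaction, and the block changed no call of a single feature.

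With the adjusted p alone the counts rose to 2408, 3156, 4552, 2918, 4090 and 2986 for the line differences from 15 to 40 days, 8943 for their average, 8380, 7981, 1326, 2372 and 895 for the 5 successive intervals, and 15362 and 15530 for 15 to 40 days in the high-oil and low-oil lines, because small changes then count. With a pseudocount of 0.1 the average gave 3451 and the intervals 2624, 2831, 478, 1132 and 332. Limma-voom gave 3701, then 2507, 2741, 396, 1044 and 313, and 320 for the interaction. A minimum of 5 RPKM, which tests fewer features, gave 1010, 1230 and 1205 at 15, 20 and 40 days and 495 for the interaction. Fitting the compared groups only, which uses fewer libraries, gave 1249 at 40 days and 0 for 35 to 40 days. It does not alter the averaged line difference, which uses all groups. Under the settings named so far, and under median-of-ratios scaling, quantile normalization and no filter, the other totals called in the 15 comparisons stayed within 1.5 times. A smaller pseudocount and limma-voom enlarge the log2 changes of low features, though this was not tested as the cause. Features higher at all 6 stages numbered 321, and 501 with a pseudocount of 0.1, and opposite changes in the lines 16 and 41.

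Leaving out 1 library gave 155 to 329 for 25 to 30 days and 101 to 339 for 35 to 40 days, outside 1.5 times, and 597 to 1063 for the interaction. Without the 3 libraries that stand apart the counts were 2320 at 40 days, 8393 and 8168 for 15 to 40 days and 1001 for the interaction. Features listed in 1 line only numbered 138, and 3 when 0 was required in the other line, 270 below 0.5 RPKM and 26 at 5 RPKM or more. Features that fell in both lines numbered 4646, and 2930 with median-of-ratios scaling and 3012 with quantile normalization. The share of rises among called annotated genes was 28.1% and 29.7% in the high-oil and low-oil lines, 45.7% and 47.3% with median-of-ratios scaling and 44.2% and 44.7% with quantile normalization. Features higher at a middle stage than at both ends moved from 67 to 111 and 108 at 30 days and from 14 to 24 and 22 at 35 days under these scalings. Features lower than at both ends moved from 91 to 55 in all with median-of-ratios scaling, from 54 to 32 at 25 days with it, and from 37 to 16 at 30 days and 4 to 1 at 35 days with either. With a pseudocount of 0.1 the features higher than at both ends from 20 to 35 days were 213, 338, 143 and 24, and those lower 138, 173, 122 and 10, against 35, 54, 37 and 4. The cause of these moves was not tested. The line difference in the share of the most abundant features was 4.72 to 5.51 percentage points over 5, 20 or 50 features, and 1.18 without Zm00001d033447, and 4.51 over each library's own 10. The other settings of the gene lists were not run, since the lists need gene names. Depth limits the microRNA precursors, which often had fewer than 10 reads in a library.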

Other observations

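Chosen after results were seen were the counts of middle stages, the tests at a distance of 50 genes, of exchanged labels and of developmental progress, and the choice of MIR168b. Some features were highest in the middle of seed filling. Averaged over lines, 260 features were called higher at 1 or more of the 4 middle stages than at both 15 and 40 days: 110 at 20 days, 175 at 25 days, 67 at 30 days and 14 at 35 days. Fewer, 91, were lower at a middle stage than at both ends. With median-of-ratios scaling these totals were 288 and 55, and with a pseudocount of 0.1 they were 483 and 342. MIR168b, the other precursor of the MIR168 family tested, had 5.84 ± 5.52 RPKM at 15 days, 30.5 ± 2.59 at 25 days and 7.4 ± 4.05 at 40 days in the high-oil line (SD, n = 3), and 2.47 ± 0.888, 19.1 ± 4.96 and 5.74 ± 0.989 in the low-oil line, where it had 24.2 ± 4.92 at 20 days. Averaged over lines, it rose between 15 and 20 days (log2 2.17, SE 0.32, adjusted p 8.6e-06, limma) and fell between 25 and 30 days (log2 -1.37, SE 0.32, adjusted p 0.013). Its change from 15 to 40 days was not called in either line (adjusted p 0.38 and 0.069, limma).

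Line differences also clustered along the numbering of the annotated gene IDs, which runs along the chromosomes in this annotation. Positions were not used here. In 54 windows of 1000 ID numbers with at least 100 tested genes, between 0% and 14.2% of the genes were called in the averaged line difference, with a median of 3.93%. Of the next tested neighbours of a called gene 15.9% were called, against 4.39% of all annotated genes. Pairs of direct neighbours, such as tandem copies, do not account for all of it, since calls 50 tested genes apart still correlated with 0.0334, above the highest of 200 shuffles, 0.0205. Uneven expression along the numbering is argued against as well: 0 of 200 shuffles within deciles of mean RPKM gave window shares as variable. Nor did the 1 other kind of call examined cluster alike, as the ratio of observed to shuffled variance of window shares was 9.38 for line calls, 5.07 times the 1.85 of the calls from 15 to 40 days in the high-oil line. A hypothesis that stays open and untested is that the lines share some chromosome segments by descent and differ in others. Sequence differences from the reference genome, which could lower alignment in the same segments of a line, were not tested either.

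The surplus of rises among features without an annotation ID was examined for 3 technical explanations. Low expression does not account for it, since annotated genes drawn to match their mean RPKM still differed in the share of rises by 41.9 percentage points in the high-oil line and 38.4 in the low-oil line. Short length does not either, with differences of 37.6 and 33.1 points after matching on length. Scaling by a total that few genes fill leaves 38.3 and 34.8 points with median-of-ratios scaling. How these features were defined is not given in the sources used here. If they were assembled from these libraries, deeper late libraries could favour late transcripts, which stays open, as does a biological origin in the stage.

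Several late libraries correlated with a library of another stage more than with their own group. High-oil 35-day replicate 1 did so with high-oil 30-day replicate 1 (0.96 against 0.944). Low-oil 35-day replicate 1 did so with low-oil 40-day replicate 3 (0.982 against 0.97). High-oil 35-day replicate 2 and high-oil 40-day replicate 1 correlated with each other (0.961) more than with their own groups (0.938 and 0.934). An exchange of these 2 labels is argued against: over features called from 15 to 40 days in the low-oil line, the 40-day library scored 1.38, above the other 5 libraries and 0.83 above the higher of the other 35-day libraries, against 0.386 for 2 SD within groups. Other exchanges were not decided, since 0 of 9 put all 6 libraries closer to their own group and neither did the labels as given. RNA integrity that acts through transcript length is argued against, since the deviation of the 35-day library had a Spearman rho of -0.06 with feature length across features (0.03 for the 40-day library). Further progress of the embryos stays open: the 35-day library scored 0.906 against 0.517 and 0.554 and the 40-day library 1.38 against 0.882 and 0.913, both ahead of their group, while the rho of their deviations with the low-oil change from 15 to 40 days was only 0.21 and 0.26. A single wrong label, or unequal uptake of water during soaking, was not tested.

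Other splits of the libraries bear on the counts of calls. For the averaged line difference, 1 of 100 splits, the real one, gave as many calls, 1634 against 634 for the next. The same held for 15 to 20 days (1479 against 623), 20 to 25 days (1483 against 801), 25 to 30 days (254 against 145) and 30 to 35 days (491 against 167), each with 1 of 100. For 35 to 40 days, 3 of 100 splits gave as many, with 276 as the highest other against 197. Most other splits mixed lines or stages within a group, which adds a real difference to the spread and lowers their counts. The replicates may also be partly technical, so these shares do not exclude chance between plants or ears. Comparisons of 3 with 3 libraries have only 10 splits, too few for a share below 0.05. Their real and highest other counts were 1603 and 15 for the line difference at 15 days, 1920 and 3 at 20 days, 2065 and 38 at 25 days, 1767 and 3 at 30 days, 2319 and 9 at 35 days, and 1929 and 868 at 40 days. They were 8834 and 1 for 15 to 40 days in the high-oil line and 9070 and 1 in the low-oil line. The split at 40 days with 868 calls points to a structure among those libraries other than the line.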
